A study of Rattus norvegicus with 9 samples.

How the data were processed

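Messenger RNA of primary neonatal rat cardiomyocytes was measured in 9 libraries: 3 with Ad-GFP, 3 with Ad-Yap1 WT and 3 with Ad-Yap1 shRNA, all in high glucose with insulin. After plating for 18 to 20 h in 10% serum, the cells had spent 14 h in 1% serum with 1 g/L glucose before the 48 h treatment. RNA was enriched with oligo(dT) beads and sequenced on a BGISEQ-500, and the strand of the library kit is not stated. The submitters' notes name HISAT2, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 with the rat build rn6, without saying which step each served. The labels also mention Ad-GFP cells without the glucose and insulin treatment, and these were not analysed here.

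The authors deposited expected counts per gene and library, which carry no normalization and of which about 90% are whole numbers to 2 decimals. The deposited TPM values were scaled within each library by the authors, and each column sums to 1000000 within rounding. Per the file headers, the authors also deposited log2 fold changes for the 3 comparisons, with p-values and q-values from DESeq2. A further deposited table repeats 36 value columns of the main table and was not used. The table has 18629 protein-coding genes, 5 symbols on several lines each, and no mitochondrially encoded gene. Symbols missing from it among the fixed lists were Arhgef17, Tcap, Mvd, Alas2 and Rigi, and the 26 mitochondrially encoded genes formed a list with no member to test.

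Expected counts were rounded to whole numbers and all 9 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with group as the only factor, TMM scaling and filterByExpr, which left 13708 genes. Each comparison used edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested, called at 0.05 with no fold minimum. The standard error (SE) of a log2 fold change is its size divided by the square root of F. The biological coefficient of variation was 7.18% and the prior degrees of freedom 6.61. TMM factors were 0.961 to 0.97 in GFP, 1.05 to 1.07 in Yap1 WT and 0.972 to 0.985 in Yap1 shRNA libraries. Levels are CPM after TMM scaling, and fold changes given as folds come from the fit unless a group had 3 counts or fewer. With 0 counts in a group, the fold was computed over a floor of 3 counts for the group. With 1 to 3 counts, the ratio has a 95% exact (Clopper-Pearson) counting interval scaled by the library sizes.

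Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over 26 lists in 3 comparisons (78 tests). Of 28 lists, 20 covered processes (YAP/TEAD targets, Hippo genes, cell cycle, fetal and hypertrophy genes, contractile and calcium handling, fatty acid oxidation, glycolysis, nuclear and mitochondrially encoded respiration, sirtuins, antioxidant genes, p53 and apoptosis, endoplasmic reticulum stress, interferon response, inflammation, extracellular matrix, cytoskeleton and adhesion, insulin and IGF signalling, cholesterol synthesis, heat shock) and 8 held markers of cardiomyocytes, fibroblasts, smooth muscle and pericytes, endothelium, macrophages, epicardium, erythroid cells and neural or glial cells. With an estimated correlation in place of the preset one, 1 list call held, that of inflammation in Yap1 WT against GFP. The deposited gene annotation gave 4891 terms of 10 to 500 tested genes, tested with camera within each comparison.

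The groups, tests, gene lists, rule for named genes and all alternatives but those named below were fixed before the data were examined. Named were Yap1, Sirt1 and Mir22hg (which has no line in the table), and the 8 largest rises and 8 largest falls against GFP. The latter were taken among called genes with a mean of at least 5 CPM, groups that do not overlap and a symbol other than a provisional one. Chance alone keeps 10% of comparisons of 3 against 3 libraries from overlapping. Up to 4 members with the lowest p were named of each list with at least 3 calls or a passing list test, and for the third comparison the YAP/TEAD members and 5 genes with opposite directions.

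The overlap of the 2 comparisons with GFP was set against 20 simulations of unchanged groups that share the control libraries. Alternatives were RLE, upper quartile and library size scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), no count filter, a stricter filter (5 CPM in 3 libraries), a fold minimum, the 6 compared libraries alone, the replicate number as a block, an estimated correlation, fry, and each library left out. Thinning to equal depth and removal of a trend with transcript length were added after seeing the data. The methods were tested on simulated data of 13708 genes. In each Yap1 group, 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. These are far fewer than the genes called in the real comparisons, so the rates may differ there. In Yap1 WT against GFP, 74.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 3.8% of calls fell on unchanged genes. At the depth of Yap1 shRNA against GFP these were 68.7%, 76.1%, 98.5% and 6.9%. Camera gave p under 0.05 for 1% of 200 unchanged lists. Each gene was simulated independently, so this rate does not cover lists of correlated genes. No library was left out of the main comparisons. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.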

Results

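Primary cardiomyocytes from the hearts of 1- to 2-day-old Sprague-Dawley rats had been kept for 48 h in 33 mM glucose with 100 nM insulin, a culture model of the diabetic heart. Adenovirus carried green fluorescent protein (GFP, the control), Yap1 (wild-type, WT) or a short hairpin RNA against Yap1 (shRNA). Yap1 is the transcriptional coactivator at the end of the Hippo pathway, which works through TEAD factors. Messenger RNA was sequenced in 9 libraries, 3 per group. Every level below is the mean of 3 libraries ± SD in reads of each gene per 1000000 assigned, after TMM scaling (CPM). The libraries held 14868180, 15368473 and 15316003 assigned reads in the GFP group. They held 11497104, 10960051 and 11057647 in the Yap1 WT group and 6357403, 6103221 and 6355406 in the Yap1 shRNA group. The mean depth of the Yap1 groups was thus 0.735 and 0.413 times that of GFP. Genes with at least 10 reads numbered 13247 to 13257 per GFP library, 13282 to 13342 per Yap1 WT library and 12425 to 12540 per Yap1 shRNA library. The 10 most abundant genes took 7.98%, 6.19% and 5.98% of the reads in the 3 groups. On the first principal component (71.5% of the variance of the 1000 most variable genes), the GFP libraries lay between -60.82 and -59.58. The Yap1 WT libraries lay between 4.4 and 19.14, and the Yap1 shRNA libraries between 48.72 and 48.93.

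The vectors moved Yap1 in opposite directions. Yap1 (NCBI gene 363014, chromosome 8, 6109474 to 6204240, minus strand, rn6 as in the submitters' notes) stood at 195 ± 4.37 CPM in GFP libraries. It was 664 ± 132 CPM with Yap1 WT, 3.41-fold higher (log2 fold change 1.77, SE 0.11, adjusted p = 1.63e-08). It was 95.6 ± 0.36 CPM with the shRNA, 2.04-fold lower (log2 fold change -1.03, SE 0.11, adjusted p = 1.93e-06). The Yap1 WT libraries were uneven, at 559, 812 and 622 CPM. On the deposited TPM the Yap1 log2 fold change was 2.89 with Yap1 WT and -0.77 with the shRNA. The labels do not state the species of the Yap1 cDNA, and reads of a cDNA from another species would be counted only in part. Sirt1 (NCBI gene 309757, chromosome 20, 26831965 to 26851587, minus strand) encodes an NAD-dependent deacetylase and, with miR-22-3p, is named in the study's title. Sirt1 rose in both groups, from 20.2 ± 0.30 CPM to 29.8 ± 4.07 with Yap1 WT (log2 fold change 0.56, SE 0.09, adjusted p = 0.00012) and to 88.9 ± 3.53 with the shRNA (2.14, SE 0.09, adjusted p = 1.56e-10). The authors' deposited log2 fold changes for the same contrasts were 1.77 and -1.03 for Yap1 and 0.57 and 2.14 for Sirt1. The host transcript of miR-22 (Mir22hg) and the microRNA itself were not analysed here.

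**Figure D1:**
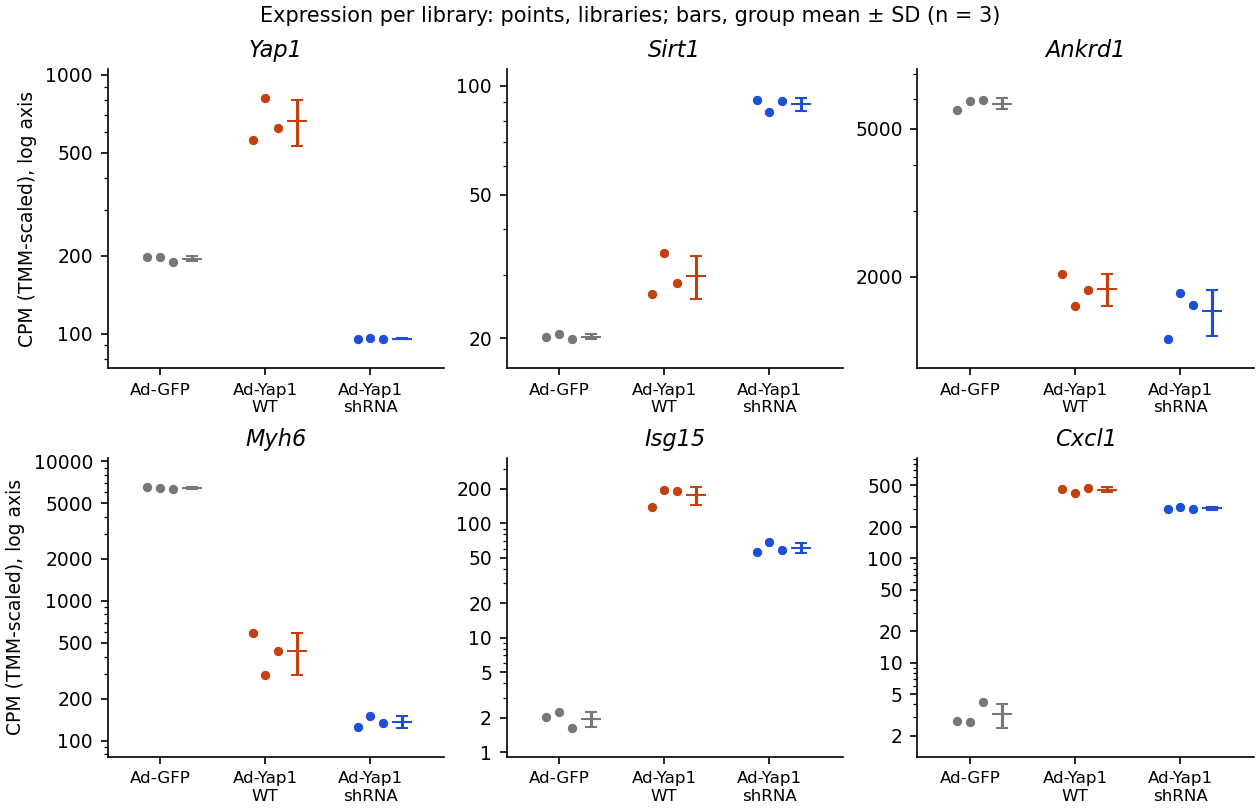
Level of 6 genes in each library (CPM after TMM scaling, log axis), with the mean and SD of the 3 libraries of each group. Yap1 was highest with Yap1 WT (664 CPM) and lowest with the shRNA (95.6 CPM), while Sirt1, Isg15 and Cxcl1 were higher, and Ankrd1 and Myh6 lower, in both Yap1 groups than in GFP.

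The first comparison asks what added Yap1 did to cardiomyocytes in high glucose and insulin. With Yap1 WT, interferon-response and chemokine transcripts rose, and the transcripts of the contractile apparatus and of mitochondrial respiration fell. Rsad2, an antiviral enzyme, rose from 0.388 ± 0.106 to 150 ± 27.5 CPM, and Cxcl1, a neutrophil chemokine, rose 141-fold, from 3.23 ± 0.85 to 457 ± 27.6 CPM. The fitted fold of Rsad2, 377, is uncertain: the log2 fold change was 8.56, against 9.62 at equal depth and 5.74 on log2(TPM + 1). Myh6, the alpha cardiac myosin heavy chain (NCBI gene 29556, chromosome 15, 33605653 to 33629730, minus strand), fell 14.6-fold, from 6434 ± 126 to 442 ± 148 CPM. The interferon, contractile and respiration lists had adjusted p = 0.385 each with an estimated correlation, and the inflammatory list 0.0479.

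Of 13708 genes tested, 8751 (63.8%) differed between Yap1 WT and GFP, 4391 higher and 4360 lower. Of these, 2273 differed at least by a factor of 2, 1260 higher and 1013 lower. The middle 50% of all fold changes lay between -0.40 and 0.40 on the log2 scale. The split by direction moved with the scaling: it was 5637 higher and 3344 lower with library size alone, and 5419 and 2894 on the deposited TPM, where the median gene shifted by 0.138 and 0.136 on the log2 scale. On log2(TPM + 1), 40 results for named genes, Yap1 included, over the 3 comparisons, moved by over 1.5 times in fold, and all kept their direction and call. The p-values in every comparison measure only the spread between these samples. The labels do not state whether the 3 replicates of a group are separate isolations, litters or dishes, whether the viruses were used at equal titre, or whether the groups were sequenced together.

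The interferon-response list rose most. All 24 measured members were higher with Yap1 WT (median log2 fold change 6.37, list test adjusted p = 1.19e-15, and adjusted p = 0.385 with an estimated correlation). The median stayed at 6.37 with the 1 member listed at 0 in GFP, Oas2, set to its lower bound. Oas2 stood at 10.2 ± 1.48 CPM with Yap1 WT. Outside the list, Oas1g (NCBI gene 100910735, chromosome 12, 42343103 to 42355139, plus strand) had 0 counts in GFP and 459 with Yap1 WT, which makes it at least 189-fold higher over a floor of 3 counts for the group. The largest rises included the antiviral GTPases Mx2 (355-fold) and Mx1 (298-fold), Oas1a (248-fold), Rtp4, not in the list (237-fold), and Usp18, the protease that removes ISG15 from proteins (207-fold, to 139 ± 26.6 CPM). Without GFP replicate 1 the log2 fold changes of Mx2, Oas1a and Rtp4 were 9.82, 9.03 and 8.48 in place of 8.47, 7.96 and 7.89. Cxcl10 rose 135-fold, the ubiquitin-like modifier Isg15 89-fold (log2 fold change 6.48, SE 0.18, adjusted p = 2.88e-11), the RNA sensor Dhx58 56.1-fold and Ifi44 20.6-fold. Paralogs such as Mx1 and Mx2, or Oas1a and Oas1g, share sequence, so the division of reads between them is uncertain. In the inflammatory list, 19 of 20 members were higher and none lower (median 3.09, adjusted p = 4.91e-12, and adjusted p = 0.0479 with an estimated correlation). Besides Cxcl1 (log2 fold change 7.14, SE 0.11, adjusted p = 4.12e-13), Cxcl3 rose 196-fold, the monocyte chemoattractant Ccl2 26.9-fold and Ccl7 68.1-fold. Cxcl6, outside the list, rose 217-fold. Reads are also hard to divide between Cxcl1, Cxcl3 and Cxcl6. Macrophage markers did not move as a list beside these genes: 2 of 9 were higher and 1 lower (median 0.02, adjusted p = 0.659). Adgre1, the macrophage marker F4/80, was 4.72-fold higher and the complement gene C1qa 3.89-fold lower. Cd14 was 1.69-fold higher, and Fcer1g did not pass the test (1.12-fold, adjusted p = 0.369).

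In the contractile and calcium-handling list, 27 of 27 genes were lower with Yap1 WT (median log2 fold change -1.73, adjusted p = 5.65e-12). With an estimated correlation the list had adjusted p = 0.385. In the wider annotation term for cardiac muscle contraction, 55 of 66 genes were lower and 5 higher. Besides Myh6 (-3.86, SE 0.19, adjusted p = 3.26e-09), myoglobin (Mb) fell 30.6-fold, phospholamban (Pln) 6.90-fold and the calcium pump Atp2a2 2.97-fold. The M-band gene Myom2, outside the list, fell 20.3-fold. All 10 cardiomyocyte markers were lower (median -1.79, adjusted p = 1.17e-05, and adjusted p = 0.385 with an estimated correlation), among them Actn2 (3.46-fold) and Tnni3 (3.44-fold). That marker list shares 9 of its 10 genes with the contractile list, so the lists are not independent. In the fetal and hypertrophy list, 8 of 12 members were lower and 3 higher (median -0.49, adjusted p = 0.0495, and adjusted p = 0.479 with an estimated correlation). Myh7, the beta cardiac myosin heavy chain, fell 5.32-fold to 1985 ± 545 CPM, Acta2 2.35-fold and Tpm2 1.98-fold. That call was lost without GFP replicate 1 (adjusted p = 0.0542), with the stricter count filter (0.0637), with the 6 compared libraries alone (0.0561) and with a trend with transcript length removed (0.0789). Myh6 and Myh7, and Actc1 and Acta1, are paralogs whose reads are hard to divide.

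In the list of nuclear-encoded oxidative phosphorylation genes, all 30 measured were lower (median -0.93, adjusted p = 3.19e-13, and adjusted p = 0.385 with an estimated correlation). In the wider annotation term for oxidative phosphorylation, 92 of 114 genes were lower and 11 higher. Cox8b, the heart and muscle isoform of a cytochrome oxidase subunit, fell 9.92-fold, Ndufv2 of complex I 2.51-fold, Sdha of complex II 2.45-fold and Atp5f1a of the ATP synthase 2.06-fold. In the fatty acid oxidation list, 21 of 28 were lower and 5 higher (median -0.55, adjusted p = 0.000723, and adjusted p = 0.385 with an estimated correlation). The fatty acid carriers Cd36 and Fabp3 fell 3.43-fold and 3.29-fold and the dehydrogenase Acadm 2.77-fold. Angptl4, a secreted inhibitor of lipoprotein lipase, rose 17.8-fold. Of 23 glycolysis genes, 15 were lower and 4 higher (median -0.31, adjusted p = 0.00911, and adjusted p = 0.442 with an estimated correlation), with Ldhb falling 4.03-fold, Pfkm 3.75-fold, Pgam2 9.63-fold and the lactate transporter Slc16a1 1.82-fold. All 17 cholesterol synthesis genes were lower (median -1.04, adjusted p = 9.93e-08, and adjusted p = 0.385 with an estimated correlation), including Insig1 (2.64-fold), Fdps (2.11-fold), Fdft1 (2.06-fold) and Sc5d (2.03-fold).

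Of 18 antioxidant genes, a list that includes NRF2 (Nfe2l2) itself, 15 were higher and 1 lower (median 0.77, adjusted p = 6.5e-06, and adjusted p = 0.385 with an estimated correlation). The heme oxygenase Hmox1 rose 11.7-fold to 1070 ± 265 CPM, Srxn1 7.29-fold, Txnrd1 3.11-fold and the cystine transporter Slc7a11 2.64-fold. Of 23 p53 and apoptosis genes, 20 were higher and 1 lower (median 0.59, adjusted p = 4.89e-06, and adjusted p = 0.24 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose 3.24-fold, the p53 ligase Mdm2 3.63-fold, Sesn2 2.64-fold and Tp53inp1 1.92-fold. Of 12 heat-shock genes, 11 were higher (median 0.98, adjusted p = 8.34e-05, and adjusted p = 0.402 with an estimated correlation), including the chaperones Hsph1 (3.58-fold), Hsp90aa1 (3.13-fold), Hspa8 (2.67-fold) and Dnajb1 (2.08-fold). The endoplasmic reticulum stress list did not pass (12 of 20 higher and 4 lower, median 0.37, adjusted p = 0.0553), although Atf3 (6.19-fold), Ppp1r15a (2.62-fold) and Chac1 (1.97-fold) rose. It passed without GFP replicate 3 (adjusted p = 0.0463), without Yap1 WT replicate 1 (0.0217) or without Yap1 WT replicate 2 (0.0467).

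The YAP/TEAD target list went both ways. Of 22 measured targets, 9 were higher and 9 lower with Yap1 WT (median 0.05, mean 0.14, adjusted p = 0.937). The list test leaned downwards against all other genes, opposite in sign to the median and mean. Igfbp3 rose 3.41-fold and Gadd45a 2.25-fold, while the usual reporter targets Ankrd1 (log2 fold change -1.66, SE 0.10, adjusted p = 1.54e-08) and Ccn2 (-0.73, SE 0.05, adjusted p = 1.22e-07) fell. Ankrd1 went from 5841 ± 200 to 1849 ± 178 CPM. Among 21 Hippo genes, 9 were higher and 7 lower (median 0.08, adjusted p = 0.665). Map4k4 and Stk4, kinases upstream of LATS, rose 1.62-fold and 1.85-fold, and Tead3 and Wwc2 fell 1.53-fold and 1.37-fold. Of 36 cell cycle genes, 12 were higher and 15 lower (median -0.18, adjusted p = 0.674). The replication licensing genes Mcm3 and Mcm6 rose 2.34-fold and 2.08-fold and Ccne2 1.73-fold, while thymidine kinase (Tk1) fell 1.66-fold. Of 7 sirtuins, 2 were higher and 3 lower (median -0.21, mean 0.01, adjusted p = 0.764). Sirt7 rose 2.18-fold, Sirt5 fell 1.58-fold and Sirt2 fell 1.15-fold, a call that ended with library size alone (adjusted p = 0.215) and on the deposited TPM (adjusted p = 0.58).

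Lists for the surroundings of the cell were mixed. Of 24 extracellular matrix genes, 7 were higher and 11 lower, and 19 were called when adjusted over the list alone (median -0.22, adjusted p = 0.665). Elastin (Eln) fell 14.3-fold, while Tnc rose 2.33-fold, Spp1 2.68-fold and Timp1 2.29-fold. Of 22 cytoskeleton and adhesion genes, 4 were higher and 11 lower (median -0.12, adjusted p = 0.0553). That median turned to 0.01 with library size alone and 0.05 on TPM, and the list passed without GFP replicate 2 (adjusted p = 0.0356), Yap1 WT replicate 1 (0.0345) or Yap1 WT replicate 2 (0.0391). Myl9 fell 2.72-fold, vinculin (Vcl) 2.06-fold, the transcription factor Srf 1.75-fold and Flna 1.70-fold. Of 18 insulin and IGF signalling genes, 7 were higher and 8 lower, and 16 were called when adjusted over the list alone (median -0.10, which turned to 0.03 and 0.05 with the same scalings, adjusted p = 0.663). The adaptor Grb10 fell 2.27-fold, Tsc22d3 fell 2.47-fold and Trib1 rose 1.92-fold. For each other list and comparison, the count adjusted over the list alone equalled the count over all genes unless another is given.

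Markers of other cell types moved unevenly with Yap1 WT. Among 9 smooth muscle and pericyte markers, 8 were lower and 1 higher (median -0.70, adjusted p = 0.00905, and adjusted p = 0.432 with an estimated correlation), including Myh11 (2.71-fold), Notch3 (2.22-fold) and Tagln (1.76-fold). Of 10 fibroblast markers, 3 were higher and 5 lower (median -0.23, and -0.37 to -0.12 as each library was left out, adjusted p = 0.727). Dcn rose 3.71-fold and Lum 2.02-fold, and Tcf21 fell 2.24-fold and Col3a1 1.60-fold. Of 9 endothelial markers, 4 were higher and 2 lower (median 0.44, adjusted p = 0.31), with Cdh5 2.26-fold, Egfl7 2.19-fold and Kdr 1.57-fold higher and Esam 1.57-fold lower. Of 8 epicardial markers, 2 were higher and 5 lower (median -1.05, adjusted p = 0.31), with Upk1b 3.42-fold and Tbx18 1.61-fold higher and Msln 3.73-fold and Upk3b 3.39-fold lower. Of 3 neural and glial markers, 1 was lower (median -0.48, and -0.46 to -0.04 as each library was left out, adjusted p = 0.582). No erythroid marker was abundant enough to test. Outside the lists, G0s2 fell 18.4-fold, Nsg2 16.3-fold, Fam180a 14-fold and Adamtsl2 13.4-fold.

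The second comparison asks what lowering Yap1 did under the same medium. No group carried a control hairpin. Effects of the hairpin vector itself thus cannot be told apart from those of lower Yap1, here or in the third comparison. Contractile and respiratory transcripts again fell, and interferon and chemokine transcripts again rose. The contractile and respiratory falls were larger than with Yap1 WT, but the interferon rise was smaller: the list medians were 4.58 and 6.37, and all 24 members were higher with Yap1 WT than with the shRNA. In the direct test between the Yap1 groups, these differences had adjusted p = 0.399 for the contractile, 0.442 for the respiration and 0.385 for the interferon list with an estimated correlation. Against GFP, the contractile, respiration, interferon and inflammatory lists had adjusted p = 0.385, 0.399, 0.385 and 0.176 with an estimated correlation. The transcription factor Hey1, a Notch target, was at 76.7 ± 5.70 CPM after 3 counts in all GFP libraries together (ratio 1120, 95% counting interval 384 to 5450). Elastin fell 105-fold, from 1645 ± 66.1 to 15.7 ± 1.70 CPM. Cdkn1a rose 9.42-fold, from 160 ± 8.08 to 1506 ± 25.4 CPM, and Myh7 fell 36.1-fold, from 10560 ± 332 to 293 ± 24 CPM.

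Of the 13708 genes, 10733 (78.3%) differed between Yap1 shRNA and GFP, 5371 higher and 5362 lower. At least by a factor of 2, 4904 differed, 2627 higher and 2277 lower. The middle 50% of fold changes lay between -0.70 and 0.75 on the log2 scale. With upper quartile scaling the split was 4732 higher and 6091 lower (the median gene shifted by -0.15), and on TPM it was 6294 and 4242 (shift 0.16). The shRNA libraries had the lowest depth, and intervals and floors cover counting error only.

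The largest rises were of genes close to absent in GFP cultures. Nell2 rose to 95.5 ± 4.66 CPM from 1, 2 and 1 counts in the GFP libraries. Its fitted fold, 931, is uncertain: the log2 fold change was 9.86, against 12.19 at equal depth and 5.46 on log2(TPM + 1). Tmem200c rose 675-fold to 162 ± 5.69 CPM and Cbln2, a synaptic organiser, 360-fold, with log2 fold changes of 9.40 and 8.49, and 6.21 and 5.76 on log2(TPM + 1). Sox21, a neural transcription factor, had 1 count in GFP (ratio 1310, interval 234 to 51800), as did Bpifb1 (ratio 399, interval 70.6 to 15800). Spata48 and the transporter Slc10a4 had ratios of 612 (169 to 5070) and 448 (123 to 3710). Among the falls, Selenbp1 had 678 counts in GFP and 0 with the shRNA, at least 94.7-fold lower over a floor of 3 counts for the group. The cardiac kinase Tnni3k fell 203-fold, Cox8b 197-fold, the proteoglycan Acan 66.7-fold and carbonic anhydrase 3 (Ca3) 54.9-fold. These folds are uncertain, since the shRNA libraries held few counts: 1, 2 and 2 for Tnni3k and 0, 4 and 1 for Cox8b. Acan had 5, 1 and 3 and Ca3 2, 1 and 2. On log2(TPM + 1) the log2 fold changes of Tnni3k, Acan and Ca3 were -4.50, -2.68 and -3.39, against -7.66, -6.06 and -5.78. Upk3b had 1 count with the shRNA (ratio 245, interval 43.7 to 9680) and Pcare 3 counts (ratio 86.9, interval 29.6 to 422). The log2 fold change of Cox8b was -7.63, and -9.27 without Yap1 shRNA replicate 2. Fitted log2 fold changes of genes with 1 to 3 counts moved as single libraries were left out: they were 10.70 for Hey1 and 11.27 for Sox21 without GFP replicate 1, 9.56 for Bpifb1 without GFP replicate 3, -10.25 for Upk3b without Yap1 shRNA replicate 1 and -10.34 for Pcare without Yap1 shRNA replicate 3, against 9.91, 9.76, 8.05, -7.66 and -6.34 with all libraries.

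Again 27 of 27 contractile and calcium-handling genes were lower (median log2 fold change -3.55, adjusted p = 5.81e-11, and adjusted p = 0.385 with an estimated correlation). The calcium buffer Casq2 fell 10.6-fold, the Z-disc gene Myoz2 13.8-fold, the troponin Tnnc1 12.6-fold and Actn2 8.42-fold. The 10 cardiomyocyte markers were all lower (median -3.59, adjusted p = 2.46e-05, and adjusted p = 0.385 with an estimated correlation), with Pln falling 25.5-fold, Mybpc3 10.4-fold and Tnnt2 8.50-fold. In the fetal and hypertrophy list, 9 of 12 were lower and 3 higher (median -1.68, adjusted p = 0.0224, and adjusted p = 0.442 with an estimated correlation). Besides Myh7 (log2 fold change -5.17, SE 0.17, adjusted p = 3.83e-11), atrial natriuretic peptide (Nppa) fell 8.28-fold, Acta1 10.1-fold and Fhl1 3.24-fold.

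All 30 oxidative phosphorylation genes were lower (median -1.38, adjusted p = 1.39e-10, and adjusted p = 0.399 with an estimated correlation). Cox6a2 fell 6.34-fold, Atp5po 4.01-fold, Ndufa4 3.14-fold and Atp5f1a 2.84-fold. Of 28 fatty acid oxidation genes, 19 were lower and 8 higher (median -1.01, adjusted p = 0.0134, and adjusted p = 0.385 with an estimated correlation). Cd36 fell 8.88-fold, Fabp3 4.06-fold and Acadm 3.52-fold, and Angptl4 rose 28.5-fold. Of 23 glycolysis genes, 16 were lower and 5 higher (median -0.47, adjusted p = 0.0178, and adjusted p = 0.442 with an estimated correlation), with Ldhb falling 10.3-fold, Pfkm 8.17-fold and Eno3 6.80-fold while the regulatory kinase Pfkfb3 rose 2.70-fold. All 17 cholesterol synthesis genes were lower (median -1.56, adjusted p = 2.21e-06, and adjusted p = 0.385 with an estimated correlation). Fdps fell 3.72-fold, Cyp51 3.71-fold, Fdft1 2.96-fold and Sc5d 2.31-fold.

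All 24 interferon-response genes were higher (median 4.58, the same with Oas2 at its bound, adjusted p = 2.26e-08, and adjusted p = 0.385 with an estimated correlation). Usp18 rose 71.6-fold, Oasl 44.8-fold, Isg15 30.9-fold to 60.9 ± 6.38 CPM and Dhx58 18.8-fold. Of 20 inflammatory genes, 18 were higher and 1 lower (median 3.24, adjusted p = 4.4e-06, and adjusted p = 0.176 with an estimated correlation). Cxcl1 rose 93.5-fold to 304 ± 9.20 CPM, Ccl7 54.4-fold, Ccl2 24.5-fold to 1103 ± 87.1 CPM and Nfkbiz, a nuclear regulator of NF-kappa-B, 10.7-fold. Beside these genes, 6 of 9 macrophage markers were lower and 1 higher (median -0.81, adjusted p = 0.205). Lyz2 fell 3.53-fold, Fcer1g fell 2.16-fold and Adgre1 rose 2.03-fold. C1qa had 3 counts with the shRNA (ratio 8.94, interval 2.92 to 44.5), and without Yap1 shRNA replicate 1 its fitted log2 fold change was -7.07 in place of -3.07.

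Of 23 p53 and apoptosis genes, 18 were higher and 2 lower (median 0.83, adjusted p = 0.000176, and adjusted p = 0.385 with an estimated correlation). Besides Cdkn1a (log2 fold change 3.24, SE 0.07, adjusted p = 2.97e-12), Mdm2 rose 13.8-fold, Sesn2 11.4-fold and Tp53inp1 6.77-fold. Of 18 antioxidant genes, 13 were higher and 2 lower (median 1.07, adjusted p = 0.00185, and adjusted p = 0.442 with an estimated correlation). Osgin1 rose 17.9-fold, Txnrd1 5.82-fold, Slc7a11 4.35-fold and Gclc, the first enzyme of glutathione synthesis, 3.64-fold. Of 12 heat-shock genes, 11 were higher (median 1.71, adjusted p = 0.000165, and adjusted p = 0.411 with an estimated correlation), including Hsph1 (12.5-fold), Hsp90aa1 (6.28-fold), Bag3 (5.55-fold) and Hsp90ab1 (3.51-fold). Of 20 endoplasmic reticulum stress genes, 15 were higher and 5 lower (median 1.07, adjusted p = 0.00759, and adjusted p = 0.442 with an estimated correlation). Ppp1r15a rose 8.03-fold, the chaperone partner Dnajb9 7.65-fold and Hspa5, the lumenal chaperone BiP, 3.61-fold to 4335 ± 21.6 CPM.

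YAP/TEAD targets were divided here too: 10 of 22 were higher and 8 lower with the shRNA (median 0.10, adjusted p = 0.764), and the median turned to -0.04 with upper quartile scaling. Ccdc80 fell 7.77-fold, while Gadd45a rose 8.60-fold, Igfbp3 3.75-fold and Lats2 1.93-fold. Ankrd1 and Ccn2 were lower with the shRNA as with Yap1 WT (log2 fold changes -1.86 and -0.93, adjusted p = 1.56e-09 and 3.89e-09). Of 21 Hippo genes, 10 were higher and 6 lower (median 0.09, turning to -0.05 with upper quartile scaling, adjusted p = 0.262). Map4k4 rose 2.98-fold, Taok1 2.97-fold, Frmd6 2.23-fold and Amotl1 2.01-fold. Of 36 cell cycle genes, 23 were lower and 8 higher (median -0.66, adjusted p = 0.0521). The proliferation marker Mki67 fell 2.40-fold, while the licensing genes Cdt1, Mcm6 and Mcm3 rose 3.31-fold, 2.82-fold and 1.90-fold. That list passed without any 1 of GFP replicates 1, 2 or 3 (adjusted p = 0.0441, 0.0394 and 0.0485) or Yap1 shRNA replicate 3 (0.0485). Of 7 sirtuins, 3 were higher and 4 lower (median -0.51, mean 0.14, adjusted p = 0.759): beside Sirt1, Sirt7 rose 3.81-fold, and Sirt3 and Sirt2 fell 2.72-fold and 1.42-fold.

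Matrix, adhesion and insulin-signalling lists did not pass with the shRNA. Of 24 matrix genes, 15 were lower and 8 higher (median -0.60, adjusted p = 0.117). The collagen crosslinker Lox fell 3.13-fold and Sparc 2.32-fold, and Tnc rose 2.78-fold. Of 22 cytoskeleton and adhesion genes, 12 were lower and 8 higher (median -0.16, turning to 0.05 on TPM, adjusted p = 0.418), with Myl9 falling 3.81-fold, Vcl 2.10-fold, Srf 1.91-fold and Itgb1 1.64-fold. Of 18 insulin and IGF genes, 9 were higher and 7 lower (median 0.31, adjusted p = 0.665), with Foxo3 rising 4.50-fold, Irs2 2.15-fold and Grb10 falling 2.24-fold.

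Other cell types' markers moved apart with the shRNA. Of 10 fibroblast markers, 8 were lower and 1 higher (median -1.56, adjusted p = 0.0184, and adjusted p = 0.399 with an estimated correlation), with Tcf21 falling 7.83-fold, Pdgfra 4.91-fold, Col3a1 4.63-fold and Postn 2.44-fold. Of 9 endothelial markers, 7 were higher and 1 lower, and 9 were called when adjusted over the list alone (median 0.93, adjusted p = 0.0741). Vwf rose 5.76-fold, Cdh5 3.85-fold, Esam 1.93-fold and Egfl7 1.91-fold, all from levels below 10 CPM in GFP. Without GFP replicate 2 the log2 fold change of Vwf was 3.17 in place of 2.53. On log2(TPM + 1) it was 0.50, and that of Cdh5 was 1.19 in place of 1.94. Of 9 smooth muscle and pericyte markers, 7 were lower and 2 higher (median -0.81, adjusted p = 0.0741): Cnn1 fell 3.66-fold, Acta2 3.17-fold and desmin (Des) 2.15-fold, while the pericyte channel Kcnj8 rose 11.2-fold. Kcnj8 had 13, 10 and 8 counts in the GFP libraries, and its log2 fold change was 2.52 on log2(TPM + 1), against 3.48. Of 8 epicardial markers, 5 were lower and 2 higher, and 8 were called when adjusted over the list alone (median -2.16, adjusted p = 0.208). Msln fell 21-fold, Lrrn4 18.4-fold, and Tbx18 rose 2.51-fold. The shRNA libraries held 4, 6 and 5 counts of Msln and 2, 2 and 2 of Lrrn4. On log2(TPM + 1) their log2 fold changes were -2.94 and -1.09, against -4.39 and -4.20. Of 3 neural and glial markers, 2 were higher (median 0.77, and 0.18 to 0.87 as each library was left out, adjusted p = 0.408).

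**Figure D2:**
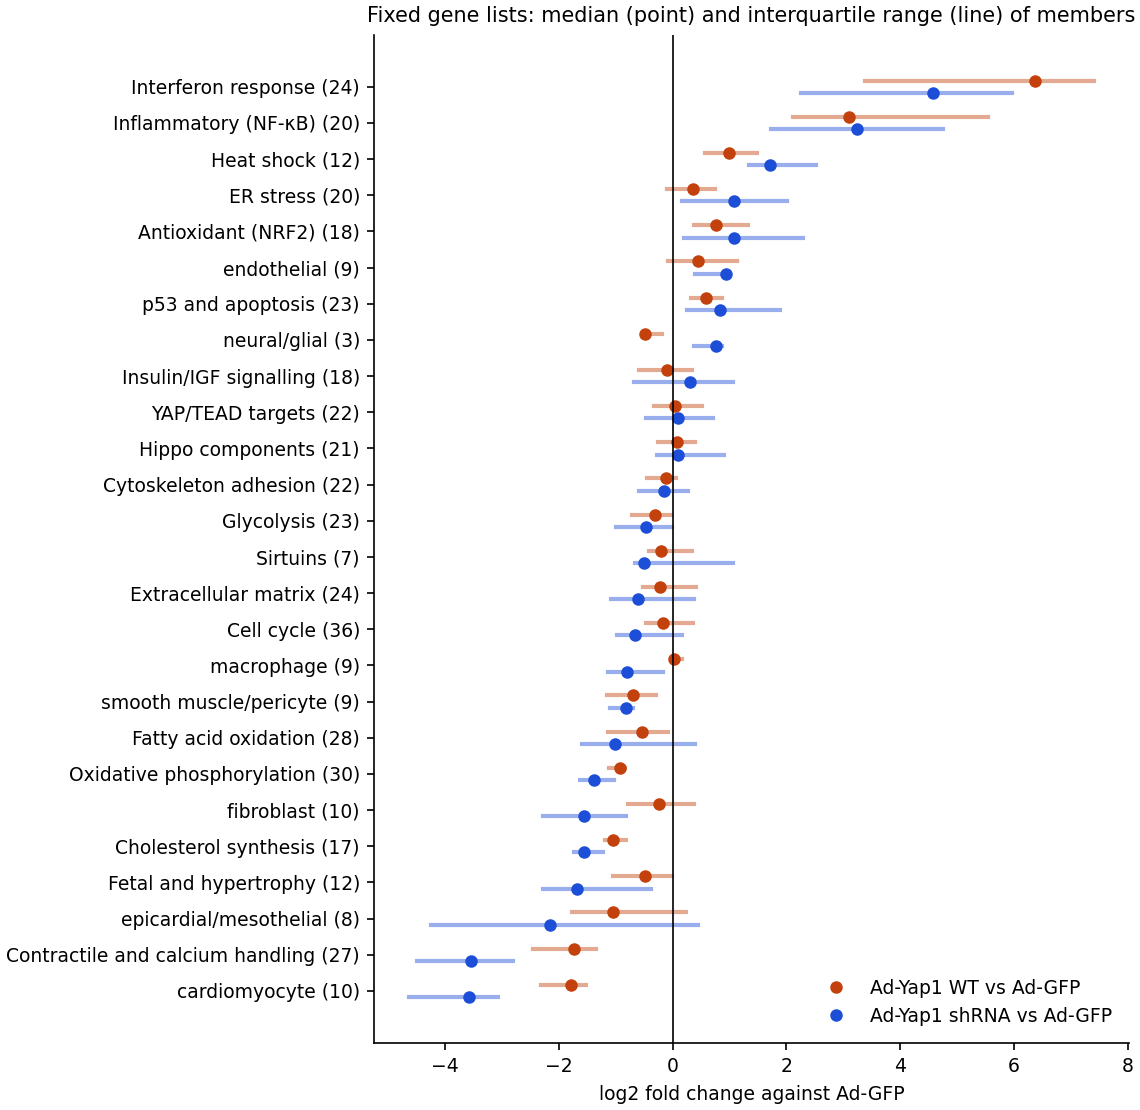
Median (point) and middle 50% (line) of the members' log2 fold change against GFP for each fixed gene list, Yap1 WT in orange and Yap1 shRNA in blue. The interferon list had medians of 6.37 and 4.58, and the contractile list -1.73 and -3.55.

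The genes that changed in both groups mostly changed in the same direction, although Yap1 itself went opposite ways. Of 7814 genes called in both comparisons, 7507 (96.1%) shared a direction, 3730 higher and 3777 lower than GFP, and 307 (3.9%) differed. Of the genes with a shared direction, 6255 (83.3%) had the larger fold change with the shRNA. In the direct test between the Yap1 groups, 4629 of them were called further from GFP with the shRNA and 481 with Yap1 WT. Across the 13708 genes, which are not independent replicates, the fold changes of the 2 comparisons correlated with Pearson's r = 0.828 and Spearman's rho = 0.836. Both comparisons use the same GFP libraries, which alone gives a correlation: in 20 simulations of unchanged groups r had a median of 0.398 (0.337 to 0.454). The observed covariance was 1.34, against a simulated median of 0.0344 and maximum of 0.0424. Independent lists of these sizes would share 1720 genes higher and 1705 lower. The 3 control libraries were not split between the comparisons, so part of the overlap may come from the shared controls.

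**Figure D3:**
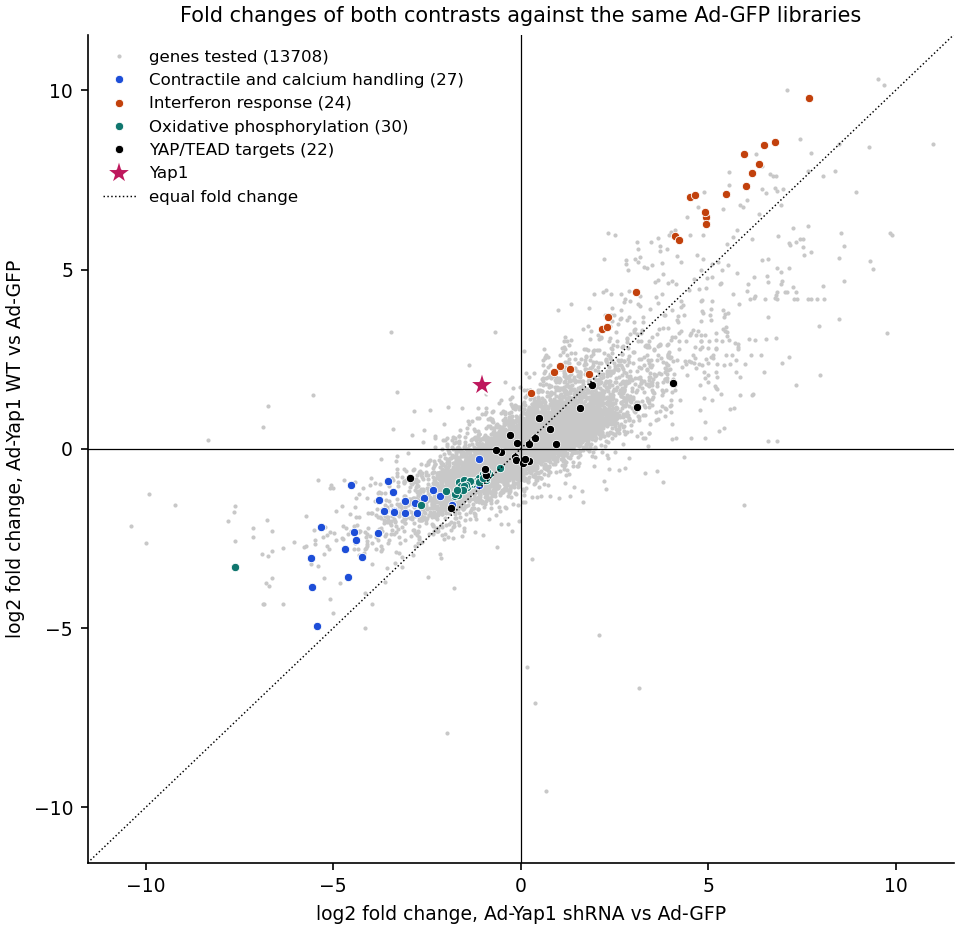
Log2 fold change of 13708 genes in Yap1 shRNA against GFP (horizontal) and Yap1 WT against GFP (vertical), with gene lists in colour, Yap1 as a star and equal fold changes as a dotted line. Most genes lay in the lower left and upper right (r = 0.828 across genes), and Yap1 in the upper left.

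The third comparison sets the Yap1 groups against each other, with no shared control library. Contractile, respiratory, cholesterol and interferon transcripts were higher with Yap1 WT than with the shRNA, and heat-shock, p53 and endoplasmic reticulum stress transcripts were lower. With an estimated correlation these list calls were lost, at adjusted p = 0.385 to 0.442. Yap1 was 6.95-fold higher (log2 fold change 2.80, SE 0.12, adjusted p = 1.59e-09, and 3.66 on the deposited TPM) and Sirt1 2.99-fold lower (-1.58, SE 0.09, adjusted p = 1.14e-08). Of 13708 genes, 8562 (62.5%) differed, 4273 higher and 4289 lower, and 1953 differed at least by a factor of 2 (876 and 1077). The split was 5561 higher and 3467 lower with upper quartile scaling (the median gene shifted by 0.18) and 5344 and 3585 with library size alone (shift 0.15).

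Of 22 YAP/TEAD targets, 8 were higher and 9 lower with Yap1 WT than with the shRNA (median -0.10, adjusted p = 0.674). The median turned to 0.04 with upper quartile scaling and 0.02 with library size alone. Ccdc80 was 4.43-fold higher, from 230 ± 17.3 CPM with the shRNA to 1017 ± 179 CPM, and Gadd45a, Lats2 and Amotl2 were 3.82-fold, 1.75-fold and 1.46-fold lower. Among genes that moved in opposite directions from GFP, the 5 with the lowest p in this comparison were Zbtb7c, Lpcat1, Arhgap28, Fbln2 and Ubtf. The matrix glycoprotein Fbln2 was 601 ± 79 CPM with Yap1 WT, 503 ± 19.5 with GFP and 124 ± 0.18 with the shRNA. Zbtb7c, a zinc finger factor, was 8.08 ± 1.58, 12.8 ± 0.44 and 127 ± 4.58 CPM in the same order. Lpcat1, Arhgap28 and the ribosomal RNA transcription factor Ubtf were 4.63-fold, 3.67-fold and 2.35-fold lower with Yap1 WT than with the shRNA. From GFP, these genes moved less with Yap1 WT than with the shRNA. Lpcat1 ran from 16.4 to 18.9 CPM with Yap1 WT, 19 to 22.1 with GFP and 78.3 to 85.2 with the shRNA. For Fbln2, Yap1 WT replicate 2 (518 CPM) lay below GFP replicate 1 (521 CPM).

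Of the 27 contractile genes, 25 were higher with Yap1 WT than with the shRNA (median 1.62, adjusted p = 2.34e-09, and adjusted p = 0.399 with an estimated correlation). All 10 cardiomyocyte markers were higher (median 1.63, adjusted p = 3.94e-05), 26 of 30 oxidative phosphorylation genes (median 0.38, adjusted p = 4.58e-06) and 13 of 17 cholesterol synthesis genes, 15 when adjusted over the list alone (median 0.52, adjusted p = 0.00149). With an estimated correlation these had adjusted p = 0.385, 0.442 and 0.442. All 24 interferon genes were higher (median 1.53, adjusted p = 5.11e-08, and adjusted p = 0.385 with an estimated correlation), as were 13 of 20 inflammatory genes with 3 lower (median 0.51, adjusted p = 0.0276, and adjusted p = 0.385 with an estimated correlation). The inflammatory call was lost with the length trend removed (adjusted p = 0.0501). Of 36 cell cycle genes, 26 were higher and 4 lower, 31 in all when adjusted over the list alone (median 0.35, adjusted p = 0.000959, and adjusted p = 0.385 with an estimated correlation). Of 24 matrix genes, 16 were higher and 4 lower (median 0.45, adjusted p = 0.00846, and adjusted p = 0.483 with an estimated correlation). Fibroblast markers (8 of 10 higher, median 1.31, adjusted p = 0.00138) and macrophage markers (6 of 9 higher, median 1.03, adjusted p = 0.0175) were higher beside them, both with adjusted p = 0.385 with an estimated correlation.

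Lower with Yap1 WT than with the shRNA were heat-shock genes (10 of 12, median -0.78, adjusted p = 0.000236), endoplasmic reticulum stress genes (14 of 20, with 5 higher, median -0.81, adjusted p = 0.0033) and p53 genes (14 of 23, with 5 higher, median -0.31, adjusted p = 0.0175). With an estimated correlation these had adjusted p = 0.422, 0.442 and 0.385. The other lists did not pass. Medians were 0.66 for the fetal and hypertrophy list (7 of 12 higher, 3 lower, adjusted p = 0.088), 0.26 for fatty acid oxidation (16 of 28 higher, 6 lower, 23 in all adjusted over the list alone, adjusted p = 0.224) and 0.19 for glycolysis (12 of 23 higher, 5 lower, adjusted p = 0.163). They were -0.28 for Hippo genes (3 of 21 higher, 10 lower, adjusted p = 0.0667), -0.43 for antioxidant genes (4 of 18 higher, 10 lower, adjusted p = 0.146) and -0.42 for insulin and IGF genes (4 of 18 higher, 10 lower, adjusted p = 0.0741). Sirtuins had a median of -0.08 (2 of 7 higher, 2 lower, adjusted p = 0.911), and cytoskeleton and adhesion genes -0.03 (6 of 22 higher, 7 lower, adjusted p = 0.674). Both turned positive with upper quartile scaling (0.06 and 0.11) and library size alone (0.03 and 0.09). Endothelial markers had a median of -0.58 (1 of 9 higher, 4 lower, adjusted p = 0.384), epicardial markers 1.04 (5 of 8 higher, 1 lower, adjusted p = 0.0628) and neural markers -0.87 (2 of 3 lower, adjusted p = 0.146). For smooth muscle markers the median was 0.08 and the mean -0.05 (3 of 9 higher, 4 lower, adjusted p = 0.981). The Hippo list passed without Yap1 WT replicate 1 (adjusted p = 0.049) and the fetal list without Yap1 WT replicate 2 (0.0481). The epicardial list passed without Yap1 WT replicate 2 (0.0481) or Yap1 shRNA replicate 1 (0.0483).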

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

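Thinning every library to the lowest total (6103220 reads) and removing a trend with transcript length were chosen after the data were seen; all other settings were planned. The number of genes called in each comparison stayed within 1.5 times its value in every scaling, filter and tool tried except a fold minimum. DESeq2 called 8003, 10203 and 7825 genes in the order of the report, no count filter 8932, 11389 and 8721, the stricter filter 7744, 9381 and 7888, and equal depth 7529, 9940 and 7931. Equal depth kept 84.1%, 91.5% and 90.6% of the called genes. Leaving out 1 library gave 7991 to 8657, 10410 to 10535 and 7934 to 8473 calls. Of 228 results for named genes, 32 fell short of a log2 fold change of 1, Sirt1 in Yap1 WT against GFP and Lats2 in both comparisons with the shRNA among them; Sirt2 in Yap1 WT against GFP alone lost its call with library size alone and on TPM. Fold changes of named genes moved by over 1.5 times in 40 results on log2(TPM + 1), 7 at equal depth, 4 with limma-voom, 3 with the length trend removed and 1 with DESeq2, and with Yap1 WT the log2 fold change of Yap1 on TPM was 2.89 against GFP and 3.66 against the shRNA. None of the genes named changed direction under any setting. A minimum log2 fold change of 1 left 2273, 4904 and 1953 genes, 1935 with a shared and 11 with an opposite direction in the 2 comparisons with GFP, by its own construction.

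Replicate numbers did not clearly pair the libraries. Correlations of their deviations from the group means ran from -0.031 to 0.094 for libraries with the same number. For libraries with different numbers they ran from -0.112 to 0.056. Not every library correlated best with its own number, but the highest values were of same-number libraries, so a weak pairing cannot be excluded. With a replicate block, 8812, 10752 and 8590 genes were called. The YAP/TEAD list test, which did not pass in any comparison, changed direction against all genes in Yap1 WT against GFP with the replicate block (median 0.043, adjusted p = 0.903) and without Yap1 WT replicate 2. Its median ran from -0.041 to 0.09 as each library was left out. In Yap1 shRNA against GFP it turned with the length trend removed (median 0.03, adjusted p = 0.938). Under fry, which tests a list without comparing it with other genes, the YAP/TEAD list passed with the shRNA (median 0.098, adjusted p = 0.00385) and between the Yap1 groups (-0.095, adjusted p = 0.000856). Also under fry the direction turned for cell cycle (-0.177, adjusted p = 0.264) and matrix genes (-0.221, adjusted p = 0.883) in Yap1 WT against GFP, sirtuins in Yap1 shRNA against GFP (-0.508, adjusted p = 0.0326) and smooth muscle markers between the Yap1 groups (0.075, adjusted p = 0.656). The last median ran from -0.021 to 0.157 as each library was left out. In the same way, medians of other lists that did not pass moved by over 1.5 times in Yap1 WT against GFP for Hippo genes (0.05 to 0.13), cell cycle (-0.24 to -0.10), endothelial (0.27 to 0.61) and macrophage markers (-0.05 to 0.10). They did so with the shRNA for Hippo (0.04 to 0.21) and insulin and IGF genes (0.17 to 0.39), and between the Yap1 groups for YAP/TEAD targets (-0.13 to -0.05), sirtuins (-0.12 to -0.002), cytoskeleton genes (-0.07 to 0.04) and neural markers (-0.76 to -0.53). The cause of these changes was not tested. With an estimated correlation, 39 list calls were lost, in the same direction. The fetal and hypertrophy list in Yap1 WT against GFP also lost its call with the stricter filter, the replicate block, the length trend removed, the 6 compared libraries alone and without GFP replicate 1 (adjusted p 0.0542 to 0.0809). The inflammatory list between the Yap1 groups lost its call with the length trend removed (adjusted p = 0.0501). The block changed 1 further list call, cell cycle in Yap1 shRNA against GFP (adjusted p = 0.0486). Cell cycle there also passed with the length trend removed (0.0348) or the 6 compared libraries alone (0.0446). In Yap1 WT against GFP, endoplasmic reticulum stress passed with library size alone (0.044) and cytoskeleton genes with the length trend removed (0.0452). Hippo genes passed between the Yap1 groups at equal depth (0.0484), and under fry 27 further list results passed. Removing mitochondrially encoded genes was not run because the table has none, and a smaller pseudocount was not run because counts were used. Depth limits the shRNA group most: 12425 to 12540 genes reached 10 reads there, against 13247 to 13257 in GFP.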

Other observations

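The tests of a response to the vectors, of the cardiomyocyte share, of the length trend with Yap1 WT and of other splits of the libraries were chosen only after the results were seen, as was the thinning to equal depth. Annotation terms outside the fixed lists gave further groups by camera with a preset correlation. Camera with an estimated correlation called 0 of 4891 terms in each comparison, with 285, 297 and 336 terms at an unadjusted p under 0.05, and the lowest adjusted p was 0.639; every term call below was thus lost. With the preset correlation, of 134 spliceosome genes, 99 were higher and 14 lower with the shRNA than with GFP (median log2 fold change 0.56, adjusted p = 2.9e-06). With Yap1 WT, 70 were higher and 12 lower (median 0.20, adjusted p = 0.00744), and 10 were higher and 86 lower with Yap1 WT than with the shRNA (median -0.33, adjusted p = 1.09e-06). Of 73 genes of ribosome biogenesis, 55 were higher and 6 lower with the shRNA (median 0.87, adjusted p = 6.47e-06). Ribosome biogenesis was higher with Yap1 WT as well by the same test (56 higher, 6 lower, median 0.40, adjusted p = 1.89e-06), and lower in Yap1 WT than in shRNA cultures (7 higher, 47 lower, median -0.43, adjusted p = 0.000328). Of 57 genes of the proteasome complex, 43 were higher and 3 lower with the shRNA (median 0.58, adjusted p = 9.12e-05) and 40 and 4 with Yap1 WT (median 0.29, adjusted p = 0.000117). Chemokine activity held 22 genes, 21 of them higher with Yap1 WT (median 4.63, adjusted p = 2.01e-10) and 19 with the shRNA (median 4.37, adjusted p = 4.9e-05).

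Of 44 genes for the degradation of valine, leucine and isoleucine, 38 fell with the shRNA (median -1.44, adjusted p = 1.37e-06) and 37 with Yap1 WT (median -0.77, adjusted p = 3.96e-08). Of 111 lysosomal genes, 70 were lower and 23 higher with the shRNA (median -0.50, adjusted p = 0.00488), and the term did not pass with Yap1 WT (adjusted p = 0.457); between the Yap1 groups 68 were higher and 15 lower with Yap1 WT (adjusted p = 0.000694). In all, 314 of 4891 terms were higher and 192 lower with Yap1 WT, 308 and 201 with the shRNA, and 174 and 201 between the Yap1 groups. Cxadr, the adenovirus receptor gene, was named after its values were seen: it rose with Yap1 WT (251 ± 5.34 against 170 ± 3.71 CPM) and fell with the shRNA (126 ± 3.89 CPM).

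Most genes called in both comparisons with GFP moved the same way, although Yap1 moved opposite ways. Unequal read number by itself is argued against: with all libraries at the lowest total, 96.8% shared a direction (6549 genes, against 214). Thinning keeps the expected proportions of genes within each library. It thus cannot address what else may have differed with depth, such as the preparation or sequencing of the groups, which was not tested. Random spread in the shared GFP libraries alone is argued against by a covariance 31.6 times the highest of 20 simulations. The simulations held no shift of the GFP group as a whole, which was not tested. A response to the Yap1 vectors rather than to Yap1, which may include the interferon list's median of 6.37 with Yap1 WT, cannot be told apart from an effect of Yap1, because vector and Yap1 changed together and reads of vector origin were not used here.

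Contractile transcripts and cardiomyocyte markers fell in both groups. A lower share of cardiomyocytes as the whole cause would raise the markers of all other cell types alike. With the shRNA their medians spanned 3.1 on the log2 scale, from epicardial (-2.16) and fibroblast (-1.56) to endothelial markers (0.93). The falls in the fibroblast and epicardial medians are not what a lower share of cardiomyocytes alone would give. Yet of 39 markers of other types, smooth muscle left out, 20 were lower and 13 higher. Of all 13708 genes, 5362 were lower and 5371 higher with the shRNA. So broad a change would give most sets of genes a mixture, and the markers cannot decide with the shRNA. A change in the share of several cell types, or in the markers within their cells, was not tested. With Yap1 WT, of 39 fibroblast, endothelial, macrophage, epicardial and neural markers, 14 were lower and 11 higher than with GFP. Of all 13708 genes, 4360 were lower and 4391 higher. Most sets of genes would thus show such a mixture, and the markers cannot decide with Yap1 WT. Smooth muscle markers were left out, since young cardiomyocytes express some of them. A trend with transcript length is argued against as the whole cause: after its removal the contractile median was -3.46 with the shRNA and -1.64 with Yap1 WT, and 27 of 27 genes stayed lower in each. An effect of Yap1 was not tested apart from the vectors, and both stay open.

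The counts of called genes were set against other splits of the same 6 libraries. In each comparison 1 of the 10 splits, the real one, gave as many genes: 8751, 10733 and 8562, against at most 0, 0 and 1 in the other splits. With 10 splits the share cannot fall below 0.1, too few for a share under 0.05.

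A hypothesis that YAP/TEAD targets are over-represented among genes that follow the Yap1 level was tested on the 150 genes higher with Yap1 WT and lower with the shRNA. Of the 22 targets tested, 0 were among them, where 0.24 would be expected (Fisher's exact test, two-sided, p = 1, upper bound of the odds ratio 16.7), so the genes were too few to decide. The hypothesis that YAP/TEAD targets are over-represented among them thus stays open.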
